A study of Sarcophaga crassipalpis with 24 samples.

How the data were processed

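RNA from flesh fly pupae (Sarcophaga crassipalpis) was compared on 24 dual-colour arrays. Per the labels, each sample was a pool of 4 individuals. Labelled antisense RNA was made by in vitro transcription from 500 ng of total RNA and carried either Cy3 or Cy5. The 4 phenotypes were non-diapause, early diapause, late diapause, and late diapause after a topical dose of hexane, with 4 pools each. Every pool carried 1 dye and was hybridised on 3 arrays, once against each of the other phenotypes, so that each of the 6 comparisons had 4 direct arrays. The hybridisations link the pools as 2 separate sets of 8 pools, and the scans fell on 2 days with 3 slides each.

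The authors deposited scanner output made with Agilent Feature Extraction 9.5. Per the file headers, each spot has a mean Cy3 and Cy5 intensity and a local background intensity, none of them normalised. The same deposited files hold processed intensities, corrected by Feature Extraction for spatial trend, background and dye, and a log10 ratio of the processed Cy5 over the processed Cy3 signal. Quality marks of 0 or 1, per the file headers, say whether a spot is well above background, saturated or an outlier. The authors also deposited a table of red and green intensities normalised within each array by loess, on a linear scale, with a lowest value near 50 in most columns. Each array held 45220 spots, of which 1417 were controls, and probes were 60 bases long. The fly design had 43553 probes. Of these, 23131 lie along the presumed coding strand of 11656 assembled contigs, and 11656 are on the opposite strand of the same contigs. Another 8560 come from contigs probed in 1 orientation. The design also had 103 probes from 26 database sequences and 103 on the opposite strand of database sequences. These classes were inferred from probe names and sequences. A further 250 probes were designed for other organisms.

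Background was corrected with normexp (offset 50), and log2 ratios of Cy5 over Cy3 were normalised within each array by loess. Both steps used limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8). The offset, added to both channels, draws the ratios of weak spots towards 1. Fold changes of weak probes, median changes and counts of 2-fold changes can therefore be too small. Spots marked as non-uniform or population outliers in the feature or its background were left out, which removed 29857 ratios (2.86%). The 16 pool values of each probe were solved from the 24 ratios by least squares within each set. They were then fitted with limma as phenotype plus dye plus set, which left 10 residual degrees of freedom and a prior of 4.28, and p values were adjusted by the Benjamini-Hochberg method. A probe was tested when it was well above background in at least 6 of the 12 channels of at least 1 phenotype. This held for 26578 probes, and 26442 of them had values in every pool. A change was called at an adjusted p under 0.05. The level of a probe in a phenotype is its mean log2 signal over 4 pools, with the SD between pools. Levels came from single channels after a further quantile normalisation of mean intensity between arrays. Differences between levels therefore need not equal the fitted changes.

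The probe filter, the fit, the rule for naming probes and most alternatives were fixed before the data were examined. The choices made later are stated here. One concerned the background: normexp failed on 3 arrays, which held up to 13 spots per channel far below their local background. All of these spots carried an outlier mark, so outliers were left out of the background fit and background outliers were left out of the ratios. That was decided after the counts of an earlier fit had been seen, which were 16912 for early diapause against non-diapause, 6245 for late against early diapause, 13525 for hexane against late diapause, 16005 for late diapause against non-diapause, 9631 for hexane against non-diapause and 15548 for hexane against early diapause. The others were the use of sequence groups and a correlation of the hexane change with the step from early to late diapause.

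The files do not pair probe identifiers with gene names, so the gene lists fixed in advance were not tested. In their place, translated probe sequences were compared with conserved motifs and with proteins of known families, in Python 3.11.15 with Biopython 1.88, numpy 2.4.6 and pandas 2.3.3. A protein match needed 14 identical residues. A group was used when at least 5 contigs matched in the coding orientation and coding matches were at least 3 times those of shuffled sequences. Of 44 groups searched, 9 were used. One of them, histones, had too few tested contigs, which left 8. The protein sequences and the merging of groups were settled after the overall counts had been seen, but before the change of any probe or group had been. A match names a family and not a gene, and several contigs may be pieces of 1 transcript. Matching database sequences are counted among the contigs of a group, and they may stem from the same transcript as an assembled contig. Matches to the 9 groups fell on 92 forward probes as printed and 1 after reverse complementing, against 2 and 39 for opposite-strand probes. For probes of contigs probed in 1 orientation the matches were 0 and 1, which leaves their strand unsettled. They were nevertheless counted as coding orientation. Groups were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry, which sets no group against other genes, beside it, adjusted over the 8 groups of each comparison.

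Probes were named by rule. A named probe was called, had the same sign on all 4 direct arrays, and was well above background in at least 10 of the 12 channels of the higher phenotype. A probe with a spot left out as an outlier on any direct array did not meet the rule. Larger changes can therefore lie outside the ranges given for named probes. From each of the comparisons of early diapause with non-diapause, late with early diapause, and hexane with late diapause, the 8 largest rises and 8 largest falls were taken, with only the probe of highest mean signal per contig considered. From each of the remaining comparisons 4 and 4 were taken. Probes of either strand could be named. Because the probes have no gene names, only 2 that rose and 2 that fell are printed with their identifiers. Contigs that match PCNA, Hsp90 or the small heat shock protein core formed groups too small to test and were singled out after their values had been seen.

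The fit was tested on simulated data with 100 probes changed at each size. It recovered 35% to 55% of 1.5-fold changes and 70% to 82% of 2-fold changes, and false calls made up 0.794% to 3.88% of the calls. The simulated noise came from Agilent's log10 ratios and not from the ratios fitted here. Far fewer of the 26442 probes were changed than were called in the data. These rates therefore need not hold for the fit of the real data. Fold changes were correlated across probes between the separate sets, so that no pool or array was shared, and 20 simulations of unchanged groups gave the correlation that a shared phenotype alone produces in the pooled values. Probes are not independent replicates. The alternatives covered background correction, normalisation, the use of Agilent's log10 ratios and of the authors' table as labelled, filters, single channels, direct arrays alone, dye and slide terms, a block for pool number, moderation, a 2-fold threshold and leaving out each pool of the phenotypes compared in turn. Added after the data were seen were the counts from each scan day alone, probes in the coding orientation alone, and omission of the 3 arrays named above. The number of arrays and pools limits the precision. Figures were drawn with matplotlib 3.10.9.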

Results

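The series profiled transcripts during the overwintering arrest of the flesh fly Sarcophaga crassipalpis, which enters diapause as a pupa when the parents and larvae experience short days. Pupae reared under 10 h of light and 14 h of dark entered diapause and were sampled at 20 days (early diapause, ED) or 50 days (late diapause, LD). A further group of late diapause pupae received 5 µl of hexane on the body surface, a treatment used to break diapause, and was sampled 24 h later (HEX). Non-diapause pupae (ND) were reared under 15 h of light and 9 h of dark, and the labels give no day for them. Temperatures were 25 °C for adults and 20 °C for larvae in all groups. Photoperiod differed along with diapause in ED and LD against ND, and age may have. The comparisons with ND cannot tell these apart. Each phenotype had 4 pools of 4 individuals. Between 16751 and 27182 of the 43553 fly probes were well above background in each channel, or 38.5% to 62.4%, and 0 to 10 probes per channel were saturated. Of the forward-strand contig probes 78.9% were tested. Pool values varied around their phenotype by an SD of 0.068 to 0.127 log2 units in 15 pools and by 0.185 in LD replicate 4.

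ED against ND asked which transcripts differ between early diapause and direct development. Heat shock protein transcripts were among the largest rises, and a DNA replication transcript was among the falls. The probe UF_Scr_AF_102374, whose translated sequence matches the Hsp70 family of ATP-dependent chaperones, was 66-fold higher in ED (log2 change 6.04 ± 0.15 SE, adjusted p = 5.63e-13, limma). Its level was 14.41 ± 0.13 (SD, n = 4) in ED and 8.41 ± 0.23 in ND. The probe UF_Scr_NF_100041, which matches the core domain of the small heat shock proteins, was 30.2-fold higher (4.92 ± 0.11, adjusted p = 3.21e-13), at 16.09 ± 0.16 in ED and 11.40 ± 0.22 in ND. The contigs that match PCNA, the sliding clamp of DNA replication, fell by 2.42 ± 0.11 and by 2.26 ± 0.12 log2 units (adjusted p = 1.25e-10 and 1.08e-09); they were singled out after their values had been seen.

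Of 9 tested contigs that match the Hsp70 family, 7 rose and 2 fell in ED against ND (camera adjusted p = 0.0231, and adjusted p = 0.34 with an estimated correlation). The camera call was lost without ND replicate 2 (adjusted p = 0.0846). The other two large rises of this family measured 6.25 ± 0.22 and 4.87 ± 0.21 log2 units. A second contig with the small heat shock protein core rose by 0.63 ± 0.08 (adjusted p = 6.1e-06). Of 5 contigs with a protein kinase active site, 4 fell and 1 rose, without a group call (adjusted p = 0.134). Of 8 trypsin-like serine protease contigs, 5 fell and 3 rose (adjusted p = 0.681), and of 14 ribosomal protein contigs 1 rose and 0 fell (adjusted p = 0.756). Of 13 contigs with the linker of C2H2 zinc fingers, which bind DNA, 4 rose and 6 fell, and of 14 mitochondrial carrier contigs, which match transporters of the inner membrane, 6 rose and 5 fell (adjusted p = 1 for both).

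The 8 largest rises by the naming rule spanned 13.3-fold to 66-fold and the 8 largest falls by it 11.5-fold to 29.3-fold. The largest of these falls belonged to UF_Scr_AF_105006, a contig with no family match, which fell by 4.87 ± 0.21 log2 units (adjusted p = 1.24e-10), from 15.84 ± 0.06 in ND to 10.89 ± 0.12 in ED. UF_Scr_AF_102402, also without a match, fell by 4.35 ± 0.16 (adjusted p = 2.19e-11). In all, 17763 of 26442 probes (67.2%) differed, 8680 higher and 9083 lower in ED. Among them 1428 differed at least 2-fold, 706 higher and 722 lower, and the median change was 1.30-fold. The count was 11613 with median centring in place of loess, 11300 among the probes above background in all 48 channels, and 1 in the authors' table as labelled, where columns did not match the scanner files of their samples.

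**Figure D1:**
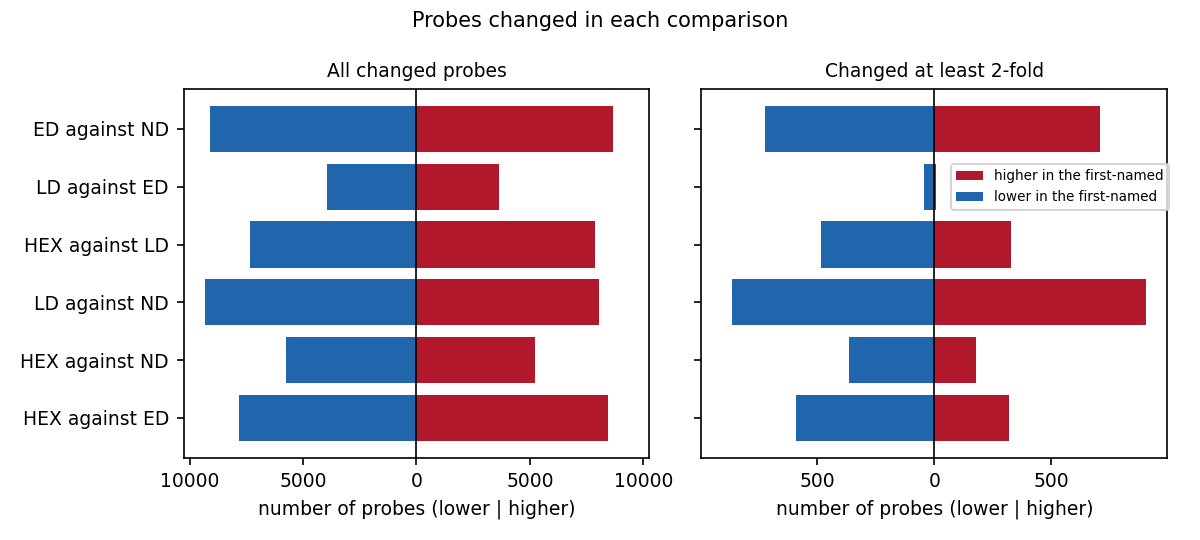
Number of probes changed in each comparison (horizontal axis, lower to the left and higher to the right of 0), for every called probe and for those changed at least 2-fold. LD against ED had 52 changes of at least 2-fold, against 1428 in ED against ND and 1768 in LD against ND.

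LD against ND asked the same of late diapause. The heat shock protein and PCNA probes printed for ED against ND differed from ND in LD as well. The Hsp70 family probe UF_Scr_AF_102374 was higher by 6.07 ± 0.15 log2 units (adjusted p = 5.41e-13) and the small heat shock protein probe UF_Scr_NF_100041 by 5.03 ± 0.11 (adjusted p = 2.68e-13), a 32.7-fold difference. The PCNA contigs fell by 2.31 ± 0.11 and by 2.16 ± 0.12. The unmatched contig UF_Scr_AF_105006 fell by 6.81 ± 0.21, or 112-fold (adjusted p = 3.79e-12). This contig and the Hsp70 family probe were named from ED against ND and stood outside the naming rule in this comparison. Their changes were larger than those that the rule gave here.

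Of the 9 Hsp70 family contigs 6 rose and 2 fell in LD against ND (camera adjusted p = 0.0178, and adjusted p = 0.105 with an estimated correlation). Of 8 contigs with the chitin-binding motif of insect cuticle proteins, 0 rose and 6 fell (camera adjusted p = 0.0404, and adjusted p = 0.105 with an estimated correlation), and of 5 protein kinase contigs 0 rose and 4 fell (camera adjusted p = 0.0178, and adjusted p = 0.105 with an estimated correlation). The cuticle call was lost without LD replicate 2 (adjusted p = 0.0567), LD replicate 3 (0.0506) or ND replicate 1 (0.0659). A cuticle contig with a log2 change of -1.04 ± 0.07 was above background in 0 of 12 LD channels, so its LD level is not resolved. Of 14 contigs that match proteins encoded by the mitochondrial genome, 1 rose and 7 fell, without a group call (adjusted p = 0.187). The naming rule gave 4 rises of 19.5-fold to 32.7-fold and 4 falls of 23.1-fold to 41.4-fold, 1 of which varied widely between pools (SE 1.43 log2 units, adjusted p = 0.0118). LD and ND differed in 17376 probes (65.7%), 8040 higher and 9336 lower in LD, and 1768 differed at least 2-fold, 905 higher and 863 lower. With median centring the split was 3686 higher and 8491 lower, and that scaling moved the median of all probes to -0.11 log2 units. The count was 11504 among probes above background in all 48 channels and 6138 in the authors' table.

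The changes of ED and LD from ND were correlated across probes. With ED against ND taken from one set of pools and LD against ND from the other, r was 0.91 both ways round, and with all pools 0.92, against 0.50 in simulations in which only the ND pools were shared. Within the 2 scan days, where ND pools were shared, r was 0.90 and 0.93. A total of 14245 probes were called in both comparisons in the same direction and 222 in opposite directions. Both comparisons used the same ND pools.

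LD against ED asked what changes as diapause proceeds. Most contigs that match mitochondrially encoded proteins or the cuticle motif were called lower in LD. Of the 14 mitochondrially encoded contigs, which match subunits of the respiratory chain and ATP synthase, 0 rose and 10 fell, with a median of -0.24 log2 units, or -0.43 with median centring (camera adjusted p = 0.000165, and adjusted p = 0.107 with an estimated correlation). Of the 8 cuticle motif contigs 0 rose and 5 fell (camera adjusted p = 0.0286, and adjusted p = 0.107 with an estimated correlation). Changes of -0.17 and -0.15 log2 units among these came from weak contigs, at 6.35 and 6.16 in LD. The latter contig was above background in 3 of 12 LD channels. The cuticle call was lost without ED replicate 1 (adjusted p = 0.0634) or LD replicate 2 (0.0597).

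The heat shock protein probes printed for ED against ND did not differ detectably between LD and ED. UF_Scr_AF_102374 measured 14.46 ± 0.14 in LD and 14.41 ± 0.13 in ED (log2 change 0.02, adjusted p = 0.924), and UF_Scr_NF_100041 measured 16.18 ± 0.15 and 16.09 ± 0.16 (0.11, adjusted p = 0.47). Of the 9 Hsp70 family contigs 3 rose and 1 fell, without a group call (adjusted p = 0.66). Contigs matching Hsp90, a chaperone of signalling proteins, rose in LD by 0.39 ± 0.08, 0.63 ± 0.09 and 0.82 ± 0.07 log2 units (adjusted p = 0.0032, 0.00028 and 8.73e-06). The unmatched contig UF_Scr_AF_105006 fell further, by 1.94 ± 0.21 (adjusted p = 3e-05), and UF_Scr_AF_102402 by 1.02 ± 0.16 (adjusted p = 0.000366). The 8 largest rises by the naming rule spanned 2.04-fold to 3.56-fold and the 8 largest falls by it 2.78-fold to 5.08-fold. For 2 of these falls the LD pools varied by an SD of 1.74 and 1.13 log2 units.

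In LD against ED 7568 probes (28.6%) were called, 3626 higher and 3942 lower, with a median change of 1.22-fold, and 52 changed at least 2-fold, 9 higher and 43 lower. The count was 777 with median centring, 60 higher and 717 lower, 4201 from the 4 direct arrays alone, 4726 with dye terms for each slide and 563 in the authors' table. It was 12664 when all 24 arrays were treated as independent, 4885 without ED replicate 4, and 5748 without LD replicate 4, the pool that stood apart.

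HEX against LD asked which transcripts respond within 24 h of hexane. The Hsp70 family and small heat shock protein probes printed for ED against ND fell and the PCNA contigs rose. UF_Scr_AF_102374 fell by 5.56 ± 0.15 log2 units, or 47.2-fold (adjusted p = 3.37e-12), from 14.46 ± 0.14 in LD to 8.93 ± 0.62 in HEX, and UF_Scr_NF_100041 fell by 4.52 ± 0.11, or 23-fold (adjusted p = 2.64e-12), from 16.18 ± 0.15 to 11.91 ± 0.10. The PCNA contigs rose by 1.88 ± 0.11 and 1.79 ± 0.12 (adjusted p = 3.91e-09 and 2.38e-08), to 11.04 ± 0.34 for the first. The unmatched contigs UF_Scr_AF_105006 and UF_Scr_AF_102402, which were low in diapause, rose by 1.91 ± 0.21 and 1.78 ± 0.16 (adjusted p = 2.55e-06 and 3.16e-07).

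**Figure D2:**
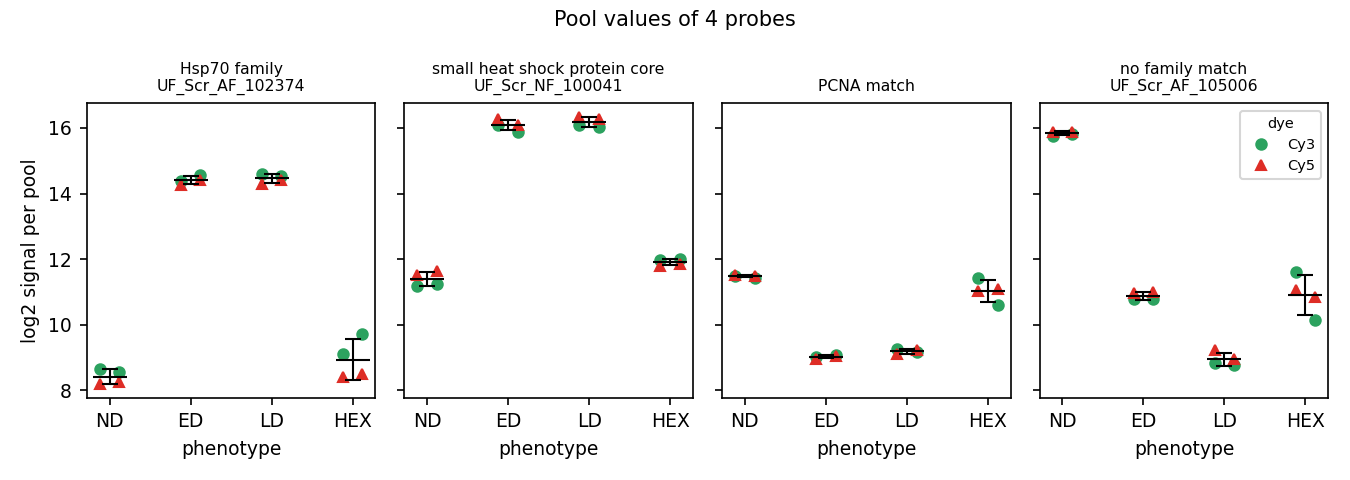
Log2 signal of each pool (points, shaped and coloured by dye) for 4 probes, with the mean and SD of 4 pools per phenotype (lines). The Hsp70 and small heat shock protein probes stood at 14.41 and 16.09 in ED and at 8.93 and 11.91 in HEX, while the PCNA probe stood at 11.48 in ND, 9.02 in ED, 9.19 in LD and 11.04 in HEX.

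Of the 9 Hsp70 family contigs 0 rose and 5 fell after hexane (camera adjusted p = 0.00745, and adjusted p = 0.219 with an estimated correlation), the others of the large changes at -5.35 ± 0.22 and -4.79 ± 0.21. The second small heat shock protein contig fell by 1.22 ± 0.08 (adjusted p = 1.54e-08). Of the mitochondrially encoded contigs 6 rose and 0 fell, without a group call (adjusted p = 0.541), and 4 of those 6 changed sign with median centring. The 8 largest rises by the naming rule spanned 3.92-fold to 10.7-fold and the 8 largest falls by it 9.02-fold to 47.2-fold. The rise of 10.7-fold and the fall of 9.02-fold came from opposite-strand probes. For that fall, 0 of the 2 other probes of the contig were called with the same sign. For a named rise of 6.87-fold the HEX pools varied by an SD of 1.28 log2 units. A total of 15179 probes (57.4%) were called, 7857 higher and 7322 lower in HEX, with a median change of 1.27-fold, and 813 changed at least 2-fold, 328 higher and 485 lower. The count was 8172 with median centring, and 0 in the authors' table fitted with limma, where 2344 probes had an unadjusted p under 0.05.

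HEX against ND asked how far treated pupae still differed from direct development. UF_Scr_AF_102374 was higher than in ND by 0.51 ± 0.15 log2 units (adjusted p = 0.0114) and UF_Scr_NF_100041 by 0.51 ± 0.11 (adjusted p = 0.00144), while the second small heat shock protein contig was lower, at -0.44 ± 0.08 (adjusted p = 0.00044). Of the 9 Hsp70 family contigs 4 rose and 2 fell, without a group call (adjusted p = 0.166). The PCNA contigs were lower by a log2 change of -0.43 ± 0.11 and -0.37 ± 0.12 (adjusted p = 0.00432 and 0.0236). UF_Scr_AF_105006 was still low, at -4.90 ± 0.21 against ND (adjusted p = 6.43e-10). Of the 5 protein kinase contigs 0 rose and 5 fell (camera adjusted p = 0.000662, and adjusted p = 0.0651 with an estimated correlation). Of 8 trypsin-like protease contigs 1 rose and 5 fell (camera adjusted p = 0.0212, and adjusted p = 0.0651 with an estimated correlation).

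Further groups were called in HEX against ND by small margins. Of the 8 cuticle motif contigs 2 rose and 5 fell (camera adjusted p = 0.0478, and adjusted p = 0.0841 with an estimated correlation), a call lost without HEX replicate 1 (0.0833) or ND replicate 1 (0.0676) and with a block for pool number (0.0538). The contig that changed by -1.03 ± 0.07 was above background in 0 of 12 HEX channels. Of 14 ribosomal protein contigs 5 rose and 0 fell (camera adjusted p = 0.0478, and adjusted p = 0.0841 with an estimated correlation), but 3 of the 5 changed sign with median centring. The ribosomal call was lost without HEX replicate 1 (0.0578), HEX replicate 2 (0.0769), ND replicate 2 (0.0663) or ND replicate 3 (0.0558). Of 14 mitochondrial carrier contigs 6 rose and 2 fell (camera adjusted p = 0.0478, and adjusted p = 0.0841 with an estimated correlation). The carrier call was lost without HEX replicate 1 (0.0578), HEX replicate 2 (0.0714), HEX replicate 4 (0.0584) or ND replicate 3 (0.0558), and with the block (0.06). The naming rule gave 4 rises of 6.9-fold to 10.4-fold and 4 falls of 15.2-fold to 143-fold. For the smallest of these rises the HEX pools varied by an SD of 1.40 log2 units. HEX and ND differed in 11002 probes (41.6%), 5243 higher and 5759 lower, and 543 differed at least 2-fold, 177 higher and 366 lower. The count was 3820 with median centring, 912 higher and 2908 lower, and 5657 from the 4 direct arrays alone.

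HEX against ED set the treated pupae against early diapause. The same heat shock protein probes were lower in HEX, UF_Scr_AF_102374 by a log2 change of -5.54 ± 0.15 (adjusted p = 3.9e-12) and UF_Scr_NF_100041 by -4.41 ± 0.11 (adjusted p = 2.53e-12), and the PCNA contigs were higher by 1.99 ± 0.11 and 1.89 ± 0.12 (adjusted p = 1.79e-09 and 1.09e-08). Of the 9 Hsp70 family contigs 2 rose and 6 fell, without a group call (adjusted p = 0.066), and 1 called contig changed sign with median centring. UF_Scr_AF_105006 measured 10.91 ± 0.61 in HEX and 10.89 ± 0.12 in ED (adjusted p = 0.916). The naming rule gave 4 rises of 6.66-fold to 17.6-fold and 4 falls of 16.2-fold to 46.4-fold. The HEX pools varied by an SD of 1.40 log2 units for the largest of these rises and 1.28 for the rise of 8.6-fold. A total of 16258 probes (61.5%) were called, 8428 higher and 7830 lower in HEX, and 910 changed at least 2-fold, 317 higher and 593 lower. The count was 9180 with median centring and 7054 in the authors' table as labelled, where 6880 of the probes called here were called with the opposite sign and 0 with the same sign.

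The hexane change ran towards the non-diapause level for most of the probes that set LD apart. Of 1768 probes that differed at least 2-fold between LD and ND, 1552 (87.8%) moved towards ND after hexane and were called, 32 moved away and were called, and 184 were not called. The median probe moved 62% of the way (quartiles 39% and 81%), and 1425 still differed from ND. The 905 probes that were higher in LD moved by a median of 70.8% and the 863 lower ones by 50.1%. The background offset compresses differences at low signal, which can raise the first share and lower the second. Whether the 2 shares differ apart from that was not tested. Probes were also chosen in 1 set of pools and their hexane change measured in the other. The median change was then 59.3% and 62.3% of the difference between LD and ND in the choosing set. In the other set that difference was a median of 105% and 92.6% of its value in the choosing set. Across all probes, HEX minus LD in one set correlated with ND minus LD in the other at r of 0.80 and 0.73 (0.80 with all pools, 0.50 in simulations in which only the LD pools were shared). Within the scan days, where LD pools were shared, r was 0.81 and 0.78. In the authors' table, as labelled, the correlation was -0.77.

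**Figure D3:**
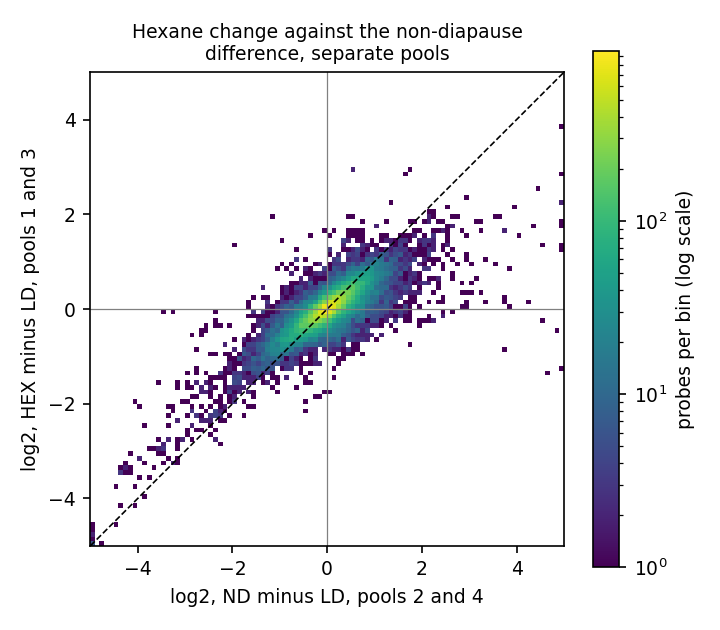
Density of probes (colour, log scale) by the log2 difference between ND and LD in pools 2 and 4 (horizontal) and the log2 change from LD to HEX in pools 1 and 3 (vertical), with the outermost bins holding values beyond the axes. The dashed line marks equal change, and the least-squares slope across probes was 0.60.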

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

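Chosen only after the results were seen were the tests of the deposited table's columns, the tests of shared late diapause pools and of scan days and slides on separate arrays, and the share of opposite-strand probes above background. The other tests of explanations below were set beforehand.

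One Hsp70 family contig, which fell in ED against ND, had a pool apart from the rest in each diapause group: ED replicate 2 measured 9.77 against 9.63 to 9.64 in the other ED pools, and LD replicate 1 measured 9.96 against 9.80 to 9.82. The mean of the cuticle motif contigs was 6.92 in HEX replicate 4 and 6.80 to 6.81 in the other HEX pools. These were 3 of 104 groups of 4 pools tested, and chance gives about 1 in 20. Among the probes designed for other organisms, which entered no comparison, 11 of 250 (4.4%) passed the background filter, against 0 of 153 negative control spots.

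The columns of the authors' normalised table did not line up with the scanner files of the samples they are labelled with. Only 2 of 24 columns correlated best with the file of their own sample, while the best match of each column was a different file, so the columns may stand under other samples than the scanner files do. The normalisation itself did not blur the match, since the median of the best correlations was 1.00 (lowest 0.79). A shift of the scanner files in place of the table would leave them poorly described by the pools, but 16 pool values explained 97.5% of their ratio variance, against at most 79.1% over 100 random reassignments and 71.3% for the table as labelled. No column was reassigned, and the table was used only as labelled; no biological explanation was tested.

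After hexane, late diapause pupae moved towards the non-diapause level. Sharing the LD pools between both differences would produce such a correlation, but with separate pools and arrays the lower r was 0.73. Differences between scan days and slides are argued against by r of 0.54 to 0.72 over 4 pairs of direct arrays with no pool, slide or scan day in common; a test within scan days, whose bounds were written before its result (0.78), shared LD pools and decided nothing. A response to the end of diapause is consistent with these values, as a hypothesis. An effect of handling, of solvent on the cuticle or of the added day stays open and untested, because no sham-treated group was analysed here.

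Of the probes on the strand opposite to the presumed coding strand, 34% passed the background filter. Signal with no matching transcript is argued against by the 4.4% of other-organism probes that passed. Among contigs with a tested opposite-strand probe, only 4.87% had no tested forward probe, which argues against contigs read in the wrong orientation. Labelled material from both strands of 1 transcript would make the pair change alike, but over the 985 opposite-strand probes above background in all 48 channels r with the forward probe was 0.67 in ED against ND, and 67 of 527 pairs called on both strands (12.7%) changed in opposite directions. It could still account for some of the pairs. Overlapping transcripts of the other strand and cross-hybridisation stay open and untested.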

How the results depend on the processing

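Some settings were tried only after the data were seen: other background fits, counts from each scan day alone, coding-orientation probes alone, omission of 3 arrays, 4 alternatives for the named probes, and those for the sequence groups. Of the alternatives for the 6 counts of changed probes, 157 stayed within 1.5 times the count reported, 22 gave a lower count and 1 a higher one. Counts follow the order ED against ND, LD against ED, HEX against LD, LD against ND, HEX against ND and HEX against ED. A 2-fold threshold gave 1428, 52, 813, 1768, 543 and 910, fewer by construction. Median centring without loess gave 11613, 777, 8172, 12177, 3820 and 9180. The authors' table as labelled gave 1, 563, 0, 6138, 11775 and 7054 with limma, and 1913, 4721, 2344, 9799, 13929 and 10289 at an unadjusted p under 0.05. Of the probes called here, 1, 86, 0, 5651, 3505 and 0 were called in the table with the same sign and 0, 73, 0, 0, 694 and 6880 with the opposite sign. Testing only probes above background in all 48 channels gave 11300 in ED against ND and 11504 in LD against ND, where fewer probes were tested. The 4 direct arrays alone gave 4201 in LD against ED and 5657 in HEX against ND, from fewer arrays. In LD against ED, slide-specific dye terms gave 4726, 24 arrays treated as independent 12664, and omission of ED replicate 4 gave 4885. For the table, median centring, slide terms and ED replicate 4 the cause was not tested. Leaving out each pool of the 2 phenotypes compared in turn gave 15824 to 17303, 4885 to 6302, 13440 to 14174, 15819 to 17051, 8843 to 10593 and 14373 to 15259. Without LD replicate 4, which stood apart, LD against ED gave 5748, HEX against LD 13737 and LD against ND 16632. Fitting normexp with outlier spots gave 16721, 5980, 13307, 15796, 9365 and 15311. Within scan day 1 the counts were 16436, 7646, 14896, 16160, 9712 and 15992, and within scan day 2 they were 19412, 10104, 16253, 19066, 14312 and 17600. The 12 arrays of a scan day were treated as independent in these fits, although arrays shared pools, so these counts can be too high. A block for pool number gave 17839, 7592, 15242, 17437, 11069 and 16334. Median r of same-number pools was -0.05 (best match in 4 of 16). Fitted dye and set terms fix the number in ED, LD and HEX, so pairing was not tested.

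The correlation of the ED and LD changes from ND (0.91) was 0.92 among probes above background in all channels, 0.92 among called probes, 0.89 with outlier spots in the normexp fit, 0.79 in the authors' table and 0.88 to 0.90 with each ED, LD or ND pool left out. The hexane correlation (0.77) was -0.77 in the authors' table and 0.72 to 0.76 with each HEX, LD or ND pool left out, with 0.72 without LD replicate 2. The cause was not tested, but the table's columns did not line up with the scanner files of their samples. All 178 alternatives for the printed probes, in ED against ND and HEX against LD, kept direction and call: pools left out, normexp with outlier spots, 3 arrays omitted, Agilent values, separate channels and slide-specific dye terms. Of 72 named changes 66 to 72 did so with pools left out, normexp with outlier spots, slide-specific dye terms, separate channels or Agilent's log ratios. The authors' table was not among these settings. With a pool left out, named changes of comparisons without that pool's phenotype were counted as kept without a test. Of the named changes, 54 of 55 with another tested probe of the contig, on either strand, had one called with the same sign. A probe named in several comparisons was counted each time. Of the checks on sequence group calls, fry aside, 90 kept the call and 30 lost it, among them every one with an estimated correlation. Fry, which sets no group against other genes, called 33 of all 48 group tests. The gene lists fixed in advance were not run. Signal over background limited the tested probes to 78.9% of the forward contig probes and 34% of the opposite-strand ones.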

Other observations

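The groups below were too small for a group test and were described after their values were seen, as were the database sequences and the correlation of the hexane change with the step from early to late diapause. The tests of other splits were set beforehand.

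Of 3 contigs matching Hsp90, 1 rose in ED against ND by 0.55 ± 0.08 log2 units and the others fell by 0.38 ± 0.09 and by 0.21 ± 0.07, of which 1 changed sign with median centring. In LD against ND all 3 rose, by 0.95 ± 0.08, 0.24 ± 0.09 and 0.61 ± 0.07 (adjusted p = 1.48e-07, 0.0339 and 2.14e-06). After hexane 1 rose by 0.50 ± 0.07 (adjusted p = 2.33e-05), 1 fell by 0.29 ± 0.09 (adjusted p = 0.0151), and the change of the third was 0.09 ± 0.08 (adjusted p = 0.386). Of 4 contigs matching elongation factor 1-alpha, which brings aminoacyl-tRNA to the ribosome, 3 rose in ED against ND and 3 in LD against ND, with medians of 0.39 and 0.54. Of 4 histone contigs, 3 fell in ED against ND by 0.42 to 1.39 log2 units and 1 rose by 0.29. Both contigs with the DEAD box of RNA helicases fell in ED against ND, by 0.51 ± 0.07 and by 0.75 ± 0.05, and rose after hexane by 0.67 ± 0.07 and 0.56 ± 0.05 (adjusted p = 7.53e-07 and 1.41e-07). Both calmodulin contigs fell in ED against ND, by 0.72 ± 0.09 and by 0.69 ± 0.09, and 1 of them rose after hexane (0.70 ± 0.09).

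The 25 tested database sequences had larger median changes than the assembled contigs, a difference that was not tested. In ED against ND 15 rose and 4 fell, with a median absolute change of 0.56 log2 units against 0.28 in the other contigs, and in LD against ND 14 rose and 5 fell, with 0.95 against 0.27. After hexane 4 rose and 12 fell, with 0.38 against 0.22. By phenotype, 199 probes were at least 2-fold higher in ND than in each of the other phenotypes and 80 at least 2-fold lower, compared with 30 and 10 for HEX, 2 and 8 for LD, and 1 and 0 for ED.

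The hexane change was only weakly correlated with the step between early and late diapause. With separate pools, HEX minus LD correlated with ED minus LD at r of 0.15 and 0.11 across probes. Probes are not independent, and the correlation was not tested against that of the non-diapause difference. Forward probes of 1 contig changed together, with r of 0.93 to 0.95 across the comparisons.

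In each comparison the 8 pools can be divided 35 ways into groups of 4, and 1 split, the real one, called as many probes as reported. The highest count of the other splits was 12 in ED against ND (17763 in the real split), 0 in LD against ED (7568), 1 in HEX against LD (15179), 30 in LD against ND (17376), 28 in HEX against ND (11002) and 0 in HEX against ED (16258). Every other split mixes the phenotypes within each group, so their difference adds to the spread and lowers the count. These splits therefore cannot decide whether chance contributed to the reported counts.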
